A study of Arabidopsis thaliana with 4 samples.

How the data were processed

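RNA from 2 add3 mutant and 2 wild-type seedling samples was hybridised to 4 Affymetrix ATH1 arrays. The deposited values are 1 MAS5 signal intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version and detection calls are not given in the sources used here. The deposited intensity values had a trimmed mean of 100 on each array, so each array had been scaled as a whole. Groups and replicate numbers came from the sample titles.

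From the 22810 probe sets of the deposited table, 64 controls were left out. The platform annotation gave 1 gene for 13513 probe sets, several for 503 and none for 8730. Of the single-gene probe sets 13436 matched the TAIR10.1 gene table, used for names, loci, gene order and the genome that holds a gene. The annotation covered 14.6% of protein-coding genes that have a symbol of their own and 63.3% of those named only by locus, so many well-known genes are unnamed here. Where a locus had several single-gene probe sets the brightest was used in gene lists. Of 47 loci with several tested probe sets, 0 had a call together with opposite signs.

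Signals were kept as scaled by the authors and turned into log2(signal + 12.5), where 12.5 is 0.25 of the median signal of 50.1. A fold change on this scale understates the change of dim genes. Probe sets with a mean signal at or above the 40th percentile (33.2) were tested. Differences came from limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, 2 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over 13648 probe sets and a threshold of 0.05. The background level of an array was the highest of 27 bacterial control probe sets, which read as unspiked. For a gene whose signals in a group did not exceed it on both arrays, the bright group's mean log2 signal was set against the mean of that level, and the ratio is given as at least N-fold. A gene above it on 1 of the 2 arrays of a group keeps its fitted difference, and is named as such.

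Gene lists with 5 or more tested members were tested with limma camera at a preset correlation of 0.01, adjusted over 40 lists. Camera with an estimated correlation and fry were alternatives, and neither called a list. With an estimated correlation camera tests on the 2 residual degrees of freedom, so few lists can pass whatever their correlation. At the preset correlation its p-values come mainly from the spread over genes, not over replicate samples. Fixed before the data were examined were 29 lists, of which 6 had enough members. Because the annotation covered few of them, 11 lists by locus and 28 families of shared symbol prefix were added after the annotation had been read and before any difference between groups was computed. The organelle-encoded lists followed the genome given in the gene table, or the gene symbol for mitochondrial genes without an entry there. The families followed symbol prefixes. All other lists were written from general knowledge and not taken from a database. The location of called loci was tested with Fisher's exact test per chromosome and with 10000 permutations of calls over windows of 50 tested loci.

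Named genes followed a rule fixed before the data were examined. It took the 15 largest rises and 15 largest falls past the threshold with 1 annotated gene and the same direction in all 4 pairs of arrays. It also took up to 4 called members of each list by size, or the 2 members with the smallest p where none was called. In addition it took 12 developmental and marker genes, where the annotation used gave a probe set for that gene alone. Families were treated in the same way, and of those not called as a list some members past the threshold are named among the closing observations.

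The procedure was tested on simulated data for the comparison of mutant with wild type, over 13648 probe sets with 200 changed and residual spreads drawn from the fit. It called 60.6% of 4-fold, 7.58% of 2-fold and 0% of 1.5-fold changes, with 0 false calls, and estimated median log2 differences of 2.00, 0.98 and 0.58. A recovery of 80% of 4-fold changes had first been asked for and was not reached, and checks of direction, estimate and false calls took its place. The simulated spreads came from 2 residual degrees of freedom and may be more uneven than the true ones. Of the 997 real calls 109 rises and 119 falls were at least 2-fold, so most were of a size that the simulation seldom called, and its rates do not describe the real comparison. It called 0 probe sets where nothing was changed, and in another simulated set it called a list shifted by 0.3 and 0 other lists. The simulated probe sets varied independently of each other, while the estimated correlation was 0.42 for the real plastid-encoded list. The simulation therefore does not show how often lists are called falsely in these data. Alternatives were another pseudocount, filter, scaling, variance model, threshold, a replicate block, unique probe sets and the omission of each array. Figures were drawn with matplotlib 3.10.9.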

Results

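Transcript levels were measured in the above-ground parts of Arabidopsis thaliana seedlings at developmental stage 1.02, when the first true leaves are visible. The labels list hypocotyls, cotyledons, meristems, true leaves and leaf primordia as the tissue. Seeds were kept at 4 °C for 4 days and plants grew at 29 °C in 24 h of light per day. The add3 group (ARRESTED DEVELOPMENT 3) was an EMS-induced mutant in the Col-3 gl1 background, where gl1 is a mutation that removes leaf hairs. The wild-type group was Col-0, so the mutation and the background differed together. Each group had 2 samples, each on 1 Affymetrix ATH1 array, a chip with 22746 non-control probe sets. Median signals were 48.4 and 48.2 on the mutant arrays and 52.1 and 51.4 on the wild-type arrays. Bacterial control probe sets that read as background reached 25.4 and 12.3 on mutant replicates 1 and 2, and 20.5 and 13.0 on wild-type replicates 1 and 2. Of the other probe sets, 65.4%, 77.6%, 72.8% and 78.5% lay above that level in the same order. The number of arrays limits the precision. Nothing in the labels says whether the replicates came from separate plantings, so the p-values measure only the spread between these samples, which may be technical.

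The comparison of mutant with wild type asked which transcripts differ in add3 seedlings grown at 29 °C. The response regulator gene RR16, a cytokinin-induced repressor of cytokinin signalling, rose from signals of 45.4 and 42.6 in wild type to 174 and 150 in the mutant (log2 difference 1.62, SE 0.15, limma adjusted p = 0.00617). AT2G38240, a jasmonate-induced oxygenase gene, fell from signals of 482 and 224 in wild type to 37.8 and 32.1 in the mutant (log2 difference -2.85, SE 0.31, limma adjusted p = 0.00933). In all, 569 probe sets rose and 428 fell among 13648 tested, and 458 of the 997 were named by a single gene in the annotation used.

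Among the 15 largest rises of probe sets with 1 annotated gene, AT1G72230, a cupredoxin gene, had signals of 1.14 and 9.54 in wild type. Its signals in the mutant were 92.1 and 82.5. The wild-type signals were not above background, and the mutant level was at least 5.33-fold higher (limma adjusted p = 0.00933). AT4G23680, a gene of the major latex protein family, rose from 114 ± 3.49 to 494 ± 9.29 (SD, n = 2 in each group, as for all values below; log2 difference 2.00, SE 0.12). The pectin methylesterase gene ATPMEPCRB rose from 55.8 ± 4.68 to 219 ± 55.0, the pectin lyase-like gene AT1G60590 from 56.5 ± 7.97 to 209 ± 43.8, and the pectate lyase gene AT1G04680 from 182 ± 29.6 to 548 ± 79.0. AT5G28500, which encodes a Rubisco accumulation factor, rose from 163 ± 28.5 to 502 ± 50.1. CHIL, a chalcone isomerase-like gene of flavonoid synthesis, rose from 31.6 ± 3.53 to 106 ± 12.0. The GDSL lipase genes AT1G33811 and AT1G29660 rose by 1.43 and 1.42 on the log2 scale, and the cupredoxin gene AT3G27200 by 1.44. The other members of this group were AT5G12110, an elongation factor gene (log2 difference 1.80), AT1G75280, an isoflavone reductase-like gene (1.44), AT1G68600, a malate transporter family gene (1.44), and AT2G34620, an mTERF family gene (1.39). Adjusted p-values of the 15 rises in limma lay between 0.00364 and 0.0432. The call of AT1G68600 was lost without mutant replicate 1 (limma adjusted p = 0.0604) and without wild-type replicate 1 (0.0626), where its log2 difference was 0.91.

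Among the 15 largest falls of probe sets with 1 annotated gene, AT5G53240, a gene of unknown function, had signals of 0.706 and 1.08 in the mutant. Its wild-type signals were 66.9 and 91.2, so it was at least 4.42-fold lower in the mutant (limma adjusted p = 0.00617). AT1G54020, a GDSL lipase gene, was also not above background in the mutant and was at least 4.67-fold lower there (limma adjusted p = 0.0196). AT5G05600, another jasmonate-induced oxygenase gene, fell from 468 ± 113 to 133 ± 97.8. The jacalin lectin genes AT1G52000, AT1G33790 and JAL23 fell by 1.87, fell by 1.72 and fell by 1.64 on the log2 scale. The threonyl-tRNA synthetase gene AT1G17960 fell from 140 ± 3.09 to 14.7 ± 7.05. Both MATE transporter genes in the group fell, AT3G23550 from 290 ± 7.85 to 62.5 ± 4.21 and AT1G66760 from 119 ± 3.84 to 34.4 ± 13.8. AT2G20670 fell from 173 ± 27.8 to 39.1 ± 12.2, and the aspartyl protease gene AT5G19120 from 517 ± 25.7 to 163 ± 1.88. The remaining falls were AT1G65370, a TRAF-like gene (log2 difference -1.67), AT2G34930, a leucine-rich repeat gene (-1.59), and AT2G30600, a BTB/POZ gene (-1.53). AT1G17960, JAL23, AT1G66760 and AT2G34930 were above background on 1 of the 2 mutant arrays, so the sizes of their falls rest partly on a signal with no usable level. Adjusted p-values of the 15 falls in limma lay between 0.00381 and 0.0493. The call of AT5G05600 was lost without wild-type replicate 1 (limma adjusted p = 0.154) or 2 (0.0783), and its log2 difference of -1.89 was -1.14 without mutant replicate 1. The call of AT2G34930 was lost without mutant replicate 1 (0.0699) or wild-type replicate 1 (0.153).

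**Figure D1:**
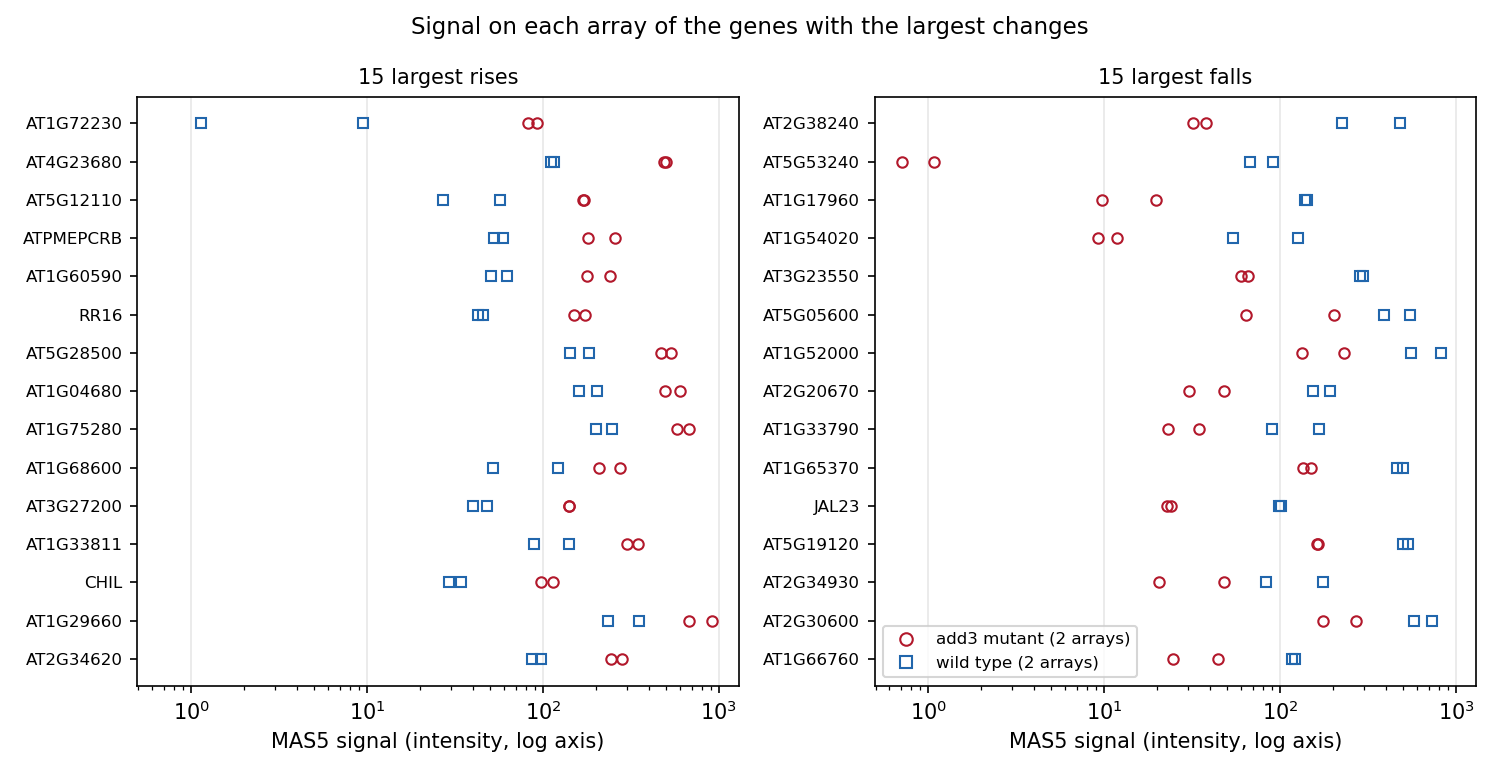
MAS5 signal (intensity, log axis) of the 15 largest rises and the 15 largest falls among probe sets with 1 annotated gene. There is 1 point per array, with circles for the 2 mutant arrays and squares for the 2 wild-type arrays. For RR16 the mutant arrays lie at 174 and 150 and the wild-type arrays at 45.4 and 42.6, and for each gene shown the groups do not overlap.

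With each array scaled to the same median, 937 probe sets rose and 319 fell, so the share of rises moved from 57.1% to 74.6%. With no filter on low signals, limma called 5 rises and 8 falls among 22746 probe sets, with 4143 at an unadjusted p under 0.05, and of the 30 genes above only AT4G23680, AT3G23550, AT1G65370 and AT5G19120 stayed past the threshold. Leaving out mutant replicate 1 or 2 gave 437 or 500 calls, and leaving out wild-type replicate 1 gave 564.

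A 2-fold change in the same direction in all 4 mutant-by-wild-type pairs was seen for 47 probe sets that were higher and 54 that were lower in the mutant. RR16, AT4G23680 and AT3G23550 are genes of this kind, since their groups lie more than 2-fold apart on each array. With 3 splits of the 4 arrays into pairs, no permutation of the arrays can give a p below 0.05. Dropping an array leaves 2 pairs in place of 4, and the counts without 1 array were 83 to 151 for higher and 97 to 123 for lower, with the highest counts without wild-type replicate 2 (151) and mutant replicate 2 (123).

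The tested nuclear genes for chlorophyll synthesis were higher in the mutant as a group. Of 23 loci in the list 7 were tested, since the others had no probe set with 1 annotated gene. Of these 7 members 6 rose and none fell, with a median log2 difference of 0.71 (limma camera adjusted p = 1.92e-06, and 0.66 with an estimated correlation). Adjusted over the list alone, 7 rose. HEME2 and HEME1, which encode uroporphyrinogen decarboxylases, rose from 263 ± 38.2 to 515 ± 43.9 and from 158 ± 7.05 to 263 ± 9.74 (SD, n = 2 each). CHLI2, a magnesium chelatase subunit gene, rose from 114 ± 4.39 to 205 ± 1.76, and GSA1, an enzyme gene of the 5-aminolevulinate step, from 335 ± 50.7 to 569 ± 6.90. Of 62 loci listed for photosynthesis 11 were tested, for the same reason. Among these 11 nuclear genes 2 rose, and 11 of the 11 estimates were above 0 (median 0.24, or 0.16 with quantile normalization, limma camera adjusted p = 0.000392, and 0.66 with an estimated correlation). Adjusted over the list alone, 5 rose. LHCB4.3, a light-harvesting protein gene, rose from 203 ± 30.4 to 383 ± 14.0, and PSBY, a photosystem II subunit gene, from 1657 ± 97.5 to 2704 ± 9.99. HEME1, CHLI2, GSA1 and PSBY lost their calls without mutant replicate 1 (limma adjusted p = 0.0567 to 0.106) or 2 (0.0582 to 0.0792), as did GSA1 without wild-type replicate 1 (0.0535) and HEME1 without wild-type replicate 2 (0.0533). The lists in this and the following paragraphs that were added once the annotation had been read, and before any difference was computed, are called added lists.

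Of the added lists, nuclear-encoded plastid ribosomal proteins had 6 rises among 10 tested members of 39 listed loci (median 0.50, limma camera adjusted p = 6.50e-06, and 0.73 with an estimated correlation). AT3G13120 rose from 831 ± 2.90 to 1439 ± 79.8, AT1G64510 from 750 ± 26.7 to 1298 ± 36.7, AT5G47190 from 465 ± 21.7 to 798 ± 4.44, and AT4G17560 from 363 ± 23.1 to 583 ± 10.6. The added list of thylakoid lumen, NDH complex and cyclic electron flow proteins had 3 rises among 17 tested members of 40 listed loci (median 0.36, limma camera adjusted p = 1.55e-05, and 0.66 with an estimated correlation). They were NdhN (log2 difference 0.72), AT4G02530 (0.70) and AT1G51400 (0.51). The 7 genes named here lost their calls without mutant replicate 1 (limma adjusted p = 0.0565 to 0.149). So did AT5G47190, AT4G17560, AT4G02530 and AT1G51400 without mutant replicate 2 (0.0553 to 0.229), and AT4G17560 and AT1G51400 without wild-type replicate 1 (0.0535 and 0.0812).

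Transcripts of the organelles' own genomes had list medians below 0, mutant minus wild type. Of 69 plastid-encoded genes tested, 11 fell and none rose, with a median log2 difference of -0.21 (limma camera, adjusted p = 1.92e-06; adjusted p = 0.73 with an estimated correlation). Adjusted over the list alone, 16 fell. The median was -0.13 without wild-type replicate 1, -0.32 without wild-type replicate 2 and -0.33 without mutant replicate 2, and -0.11 with median scaling. The weakest pair of arrays gave -0.048, within the 0.17 by which the wild-type arrays differed. The cytochrome b559 gene psbE fell from 4005 ± 230 to 1742 ± 140, the ribosomal protein genes rpl20 and rps15 from 1619 ± 508 to 678 ± 99.8 and from 513 ± 91.2 to 216 ± 13.0, and the RNA polymerase gene rpoC2 from 751 ± 86.9 to 360 ± 55.9. Of 12 mitochondria-encoded genes, 3 fell and none rose (median -0.47; limma camera, adjusted p = 2.95e-05; adjusted p = 0.73 with an estimated correlation). Adjusted over the list alone, 5 fell. The cytochrome oxidase gene cox1 fell from 344 ± 68.8 to 131 ± 1.15, and the NADH dehydrogenase genes nad5 and nad4 fell by 0.90 and fell by 0.62 on the log2 scale, with nad5 above background on 1 of the 2 mutant arrays. Both calls were lost without mutant replicate 1 (limma adjusted p = 0.165 for nad5 and 0.158 for nad4) and wild-type replicate 1 (0.130 and 0.0814), that of nad4 without mutant replicate 2 (0.106) and that of nad5 without wild-type replicate 2 (0.0810). Organelle transcripts have short or no poly(A) tails. The 5S ribosomal RNA control was also lower in the mutant (39.5 and 38.0 against 182 and 78.0). The 25S control overlapped between the groups (43.1 and 118 against 45.7 and 105). The 3' to 5' signal ratio of 1 set of actin controls was 3.1 and 3.2 on the mutant arrays and 4.49 and 2.71 on the wild-type arrays, that of the other set was 5.47 and 7.18 against 5.04 and 7.23, and the plastid-encoded median was 0.17 higher on wild-type replicate 1 than on replicate 2.

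**Figure D2:**
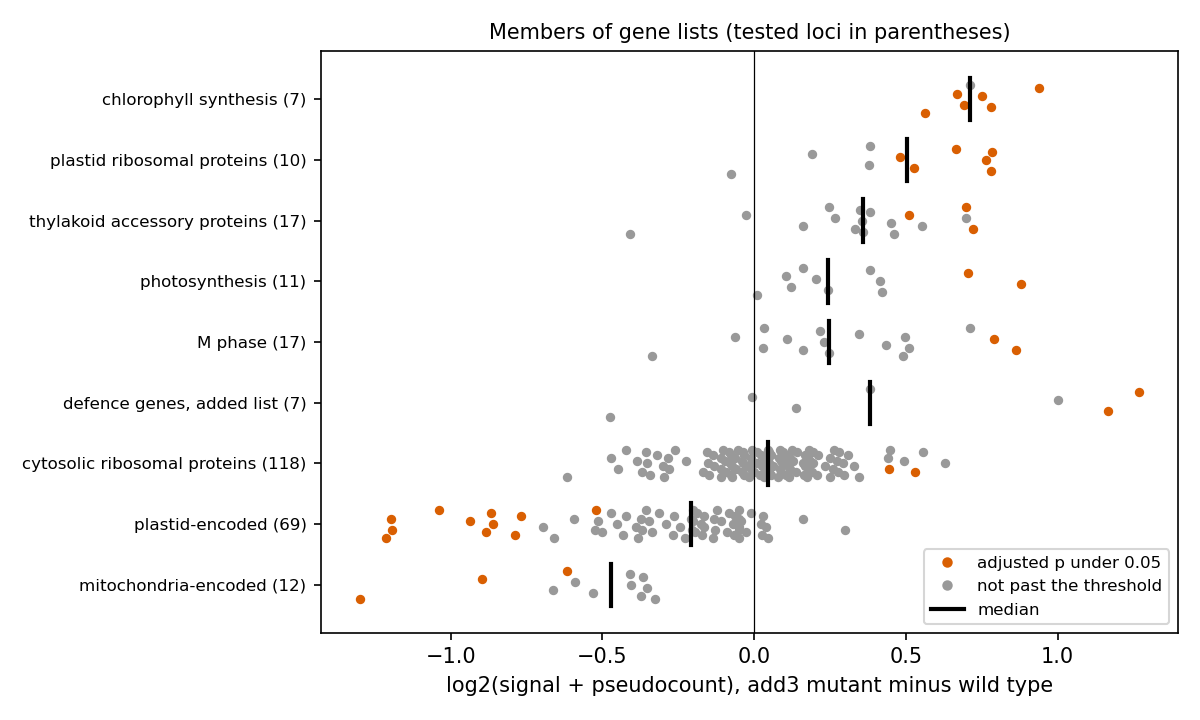
Log2 difference between add3 mutant and wild type of each tested member of 9 gene lists (x axis, log2 of signal plus pseudocount), with 1 point per locus, orange where the adjusted p passed the threshold, and a black bar at the median. The medians of chlorophyll synthesis (0.71) and plastid ribosomal proteins (0.50) lie above 0, those of the plastid-encoded (-0.21) and mitochondria-encoded lists (-0.47) lie below 0, and the cytosolic ribosomal protein median of 0.05 falls below 0 with quantile normalization.

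Among genes of cell division, the added list of M-phase proteins had 2 rises among 17 tested members of 56 listed loci (median 0.25, limma camera adjusted p = 0.00441, and 0.66 with an estimated correlation). AT5G16250 rose from 208 ± 45.9 to 385 ± 18.5 and AT4G15830 from 70.0 ± 11.6 to 130 ± 9.49. The call was lost without wild-type replicate 2 (median 0.14, limma camera adjusted p = 0.084), and the median was 0.37 without wild-type replicate 1. AUR1, a mitotic kinase gene, had a log2 difference of 0.50 (limma adjusted p = 0.101), AUR2 0.11 and PRL, a subunit gene of the replication helicase, 0.49 (0.0717). The added list of replication fork proteins, which holds PRL and POLA3 (0.47), was not called (median 0.13; limma camera, adjusted p = 0.329), nor were histones (0.19; adjusted p = 0.329), where AT2G37470 rose by 0.64 and AT2G30620 fell by 0.52 on the log2 scale. The calls of these 2 genes were lost without any 1 of the 4 arrays (limma adjusted p = 0.0637 to 0.211). AT5G16250 lost its call without mutant replicate 1 (0.0724) or wild-type replicate 1 (0.0561), and AT4G15830 without either (0.0565 and 0.0834) or mutant replicate 2 (0.10).

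The added list of pathogen-response genes had 2 rises among 7 tested members of 62 listed loci (median 0.38, limma camera adjusted p = 0.0228, and 0.73 with an estimated correlation). Both rises were genes for secreted proteins and not for receptors, the lipid transfer protein gene AT5G55450 (39.0 ± 1.48 to 113 ± 29.1) and the chitinase gene AT2G43620 (75.8 ± 1.66 to 189 ± 51.6). The call was lost without mutant replicate 2 (limma camera adjusted p = 0.103), without wild-type replicate 2 (0.164) and with no filter (0.0692), where the median was 0.065. Of 23 gene families formed from shared symbols and tested, the serine carboxypeptidase-like family was called (1 rise, scpl50, among 15; median 0.26; limma camera, adjusted p = 0.00762; adjusted p = 0.66 with an estimated correlation), but not without wild-type replicate 2 (0.0857), and its median was 0.14 with no filter. AT2G43620 lost its call without wild-type replicate 1 (limma adjusted p = 0.0561) or 2 (0.0518), and scpl50 without mutant replicate 1 (0.0892) or 2 (0.124) or wild-type replicate 2 (0.0833). TIR-domain resistance genes were not called (30 tested, none changed, median -0.14; limma camera, adjusted p = 0.478), and their members with the smallest p were AT1G69550 (0.52) and AT1G72860 (-0.41).

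Genes for cytosolic ribosomal proteins showed no shift past the threshold: 2 of 118 rose, AT2G37600 and AT3G04840, and none fell (median 0.05; limma camera, adjusted p = 0.279). The call of this list appeared without mutant replicate 1 (median 0.10, adjusted p = 0.0207) and without wild-type replicate 1 (0.12, adjusted p = 0.000691). Ribosome biogenesis factors (29 tested, median -0.02; adjusted p = 0.961) included IMP4 (-0.34) and AT5G05450 (-0.33). Class III peroxidase genes changed in both directions: AT5G51890, AT5G64120 and AT3G28200 rose by 0.98, 0.96 and 0.61 on the log2 scale, and AT3G21770 fell by 0.88, with no call for the list of 15 (adjusted p = 0.329). Of 7 heat-inducible chaperone genes, the small heat shock protein gene AT4G21870 fell from 1457 ± 296 to 600 ± 206 (list adjusted p = 0.64). AT2G37600, AT3G04840 and AT3G28200 lost their calls without any 1 of the 4 arrays (limma adjusted p = 0.0642 to 0.264). AT3G21770 lost its call without mutant replicate 2 (0.0792) or wild-type replicate 1 (0.0801) or 2 (0.0543), and AT4G21870 without wild-type replicate 2 (0.0742). Cell wall expansion genes (5 tested, adjusted p = 0.298) gave log2 differences of 0.64 for EXPA8 and 0.60 for XTH18, and auxin genes (5 tested, adjusted p = 0.81) gave -0.64 for GH3.17 and 0.30 for IAA29, none past the threshold.

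Lists with under 5 tested members were not tested as lists. In those fixed before the data were examined, RR16 was the tested cytokinin gene, and DFR, an anthocyanin synthesis gene, fell from 160 ± 6.56 to 86.5 ± 2.71 (limma adjusted p = 0.0188). No other tested member of these lists passed the threshold. In symbol families of this size, the glutathione transferase gene GSTU20 and LCR68 rose by 0.63 and 0.65 on the log2 scale, and the gene named LCR fell by 0.64. LCR lost its call without any 1 array (limma adjusted p = 0.0519 to 0.133), GSTU20 without mutant replicate 1 (0.112) or 2 (0.116), LCR68 without these (0.0776 and 0.159) or wild-type replicate 1 (0.0783), and DFR without mutant replicate 2 (0.0587) or wild-type replicate 1 (0.0569). The leaf polarity genes YAB5 and YAB3 had log2 differences of -0.54 and -0.38, the meristem gene LAS -0.15, the trichome gene SIM -0.08, the gibberellin receptor gene GID1A -0.59, the clock gene GI -0.43 and the defence regulators WRKY53 and SAG101 0.56 and -0.20. The cold-regulated genes COR15B and COR47 gave 1.02 and 0.37, the ER chaperone genes CRT1b and ATERDJ3B -0.38 and -0.32, and the glucosinolate genes AT2G31790 and BCAT4 0.46 and 0.35. The touch-induced gene STZ gave 0.55, the senescence gene WRKY6 0.24, the polymerase gene ICU2 0.12, and the ribosomal protein genes AT3G09630 and AT5G02870 0.23 and 0.16. Of markers of other tissues, the root marker PYK10 gave 0.32, the guard cell marker AT1G22690 0.39, the stomatal gene FMA -0.23 and the xylem gene GUT2 -0.26. CLV3, a stem cell marker, was below the filter, with signals of 2.54 and 1.56 in the mutant and 21.7 and 3.97 in wild type. The heat shock, jasmonate, seed and flowering lists had no tested member.

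The level of GL1, as a check of the gl1 background, was not analysed here, and neither were GL2, STM, WUS, KNAT1, AS1, ANT, CYCB1-1, HSP101, PR1 and RBCS1A. The annotation used gave no single-gene probe set for these genes, which does not show whether the array measures them. A set of array controls gave a GAPDH 3' to 5' ratio of 1.15 and 1.28 on the mutant arrays and 1.38 and 1.26 on the wild-type arrays, and a ubiquitin ratio of 2.12 and 2.29 against 3.09 and 2.21. The 25S ribosomal RNA control read 43.1 and 118 on mutant replicates 1 and 2, and 45.7 and 105 on wild-type replicates 1 and 2. The 5S ribosomal RNA control read 39.5 and 38.0 in the mutant and 182 and 78.0 in wild type.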

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

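The 19 Arabidopsis control probe sets on the array took no part in the comparison of groups. In 7 of them both mutant arrays lay above both wild-type arrays, and in 2 both lay below. Those below were the 5S ribosomal RNA control, with 39.5 and 38.0 in the mutant against 182 and 78.0 in wild type, and a control named U12639. The latter read 14.0 and 6.28 against 16.8 and 15.7, near background. Chance gives 16.7% in each direction. The groups did not overlap in 57.1% of all tested probe sets, both directions counted together. The number of such controls therefore does not stand out, and several read the same transcript. In log2 signal, mutant minus wild type, the actin middle-region sets differed by 0.39 and 0.26, the GAPDH 5' sets by 0.19 and 0.39, the GAPDH middle set by 0.28, the GAPDH 3' set by 0.27 and a ubiquitin 3' set by 0.36. They were listed because a signal outside the tested probe sets lay above the wild-type level, and no explanation was tested.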

How the results depend on the processing

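The crossed pairing was chosen after seeing the data. All other settings were listed before. Of 81 named genes past the threshold, 5 stayed past it under all alternatives run, 42 under all but the omission of the filter, and 61 under all but that and the omission of an array; none changed sign. The omission of the filter ended 76 of these calls, and limma's prior degrees of freedom fell from 5.23 to 3.39 there; the cause was not tested.

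Against 569 rises and 428 falls, no filter gave 5 and 8, eBayes without trend 308 and 247, a threshold of 0.10 gave 1038 and 929, and a 2-fold minimum 109 and 119, while median scaling gave 937 rises; the cause was not tested for filter, trend or scaling. Without 1 array the rises ranged from 232 to 506 and the falls from 205 to 311, where a group of 1 array is assumed to vary like the other. The counts of 2-fold changes in all pairs ranged from 83 to 151 for rises and from 97 to 123 for falls, with fewer pairs to satisfy. Lists called higher were 4 to 8 without 1 array, and lists called lower were 2. Camera with an estimated correlation called 0 higher and 0 lower lists, with a smallest adjusted p of 0.66, and fry 0 and 0, with a smallest adjusted p of 0.0699.

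The replicate numbers are not known to pair the samples, and same-numbered arrays did not deviate together across tested probe sets (r = -0.12). Some array readings did follow the replicate number. The 25S ribosomal RNA control read 43.1 and 45.7 on the replicate 1 arrays, against 118 and 105 on the replicate 2 arrays. The background level was 25.4 and 20.5 against 12.3 and 13.0. A batch by replicate number is therefore not excluded. With the replicate block, 501 probe sets rose and 377 fell. With the crossed pairing as a block, 1050 rose and 859 fell.

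Uncalled values that changed sign were list medians and single genes. Without 1 array the median ranged from -0.38 to 0.23 for auxin genes, -0.043 to 0.12 for cytosolic ribosomal proteins, -0.083 to 0.023 for ribosome biogenesis factors, -0.17 to 0.055 for chaperones, and -0.049 to 0.22 for class III peroxidases. With quantile normalization it was -0.025 for cytosolic ribosomal proteins, 0.016 for biogenesis factors and 0.011 for chaperones. With no filter it was -0.047 for peroxidases, and -0.010 for biogenesis factors, where camera turned upward. Without 1 array IAA29 ranged from -0.12 to 0.71, WRKY6 from -0.17 to 0.65 and STZ from -0.042 to 1.14, and SIM was 0.0026 with median scaling. The largest window of called loci held 12, and 10 or 9 with the 5% smallest p among rises or falls, where the permutation p of 0.0346 became 0.121 and 0.41; the cause was not tested. Signals at or below their own array's background level, at most 25.4, have no usable fold.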

Other observations

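Chosen after the result was seen were the tests of the organelle-encoded lists under other scalings, the use of control ratios other than that of 1 set of actin controls, and the test of a single array by the size of the pair medians. The lists of jasmonate-inducible and sugar-starvation-inducible genes were written after the largest falls had been seen, leaving those genes out, and their values without mutant replicate 1, mutant replicate 2 or wild-type replicate 2 were added after seeing the data.

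Genes named only through symbol families also changed, and those given here were chosen after their values were seen. UGT76C2, which encodes a glucosyltransferase that inactivates cytokinins, rose from 42.4 ± 1.99 to 118 ± 13.6 (SD, n = 2 each; log2 difference 1.25, limma adjusted p = 0.0115), while UGT85A2 and UGT85A4 of the same symbol family fell by 0.98 and fell by 0.76 on the log2 scale. GH9B13, an endoglucanase gene, fell from 280 ± 13.0 to 93.3 ± 4.18, while GH9B8 and GH9C2 of the same family rose by 0.99 and 0.66 on the log2 scale. The MADS-box gene AGL87 rose from 41.0 ± 0.568 to 104 ± 2.65, the peptide gene RALFL32 from 43.0 ± 6.97 to 95.9 ± 4.60, the beta-glucosidase gene BGLU44 from 423 ± 39.3 to 839 ± 57.1, and the vacuolar sugar transporter gene SWEET17 fell from 236 ± 10.6 to 143 ± 17.3. GH9C2, SWEET17 and UGT85A4 lost their calls without any 1 of the 4 arrays (limma adjusted p = 0.0533 to 0.172), GH9B8 without mutant replicate 1 (0.114) or wild-type replicate 1 (0.0828), and RALFL32 without mutant replicate 2 (0.0623). These families were not called as lists.

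No chromosome held a share of called loci that passed the test, with a smallest Benjamini-Hochberg adjusted p of 0.379 over 5 Fisher's exact tests, two-sided. Among 7233 loci, the densest window of 50 held 12 of the 441 called, on chromosome 2 between AT2G36410 and AT2G38240 (permutation p = 0.0346 over 10000 permutations, 1-sided). With the 5% smallest p among rises or falls in place of the calls, no window passed (permutation p = 0.121 and 0.41). The mutation and the Col-3 gl1 background could not be separated in this design.

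With a preset correlation, camera called 4 lists of nuclear genes for plastid proteins higher and both organelle-encoded lists lower in the mutant. Each call was lost with an estimated correlation (camera adjusted p = 0.66 to 0.73) and with fry. The estimated correlation was -0.15, -0.02 and 0.04 for the chlorophyll, photosynthesis and thylakoid lists. For the plastid ribosomal, plastid-encoded and mitochondria-encoded lists it was 0.32, 0.42 and 0.35. Camera with an estimated correlation has only 2 residual degrees of freedom. The losses of the chlorophyll, photosynthesis and thylakoid lists thus cannot be read as an effect of correlation among genes. For the other lists, correlation and the few degrees of freedom could not be told apart. Array scaling as the whole cause was argued against for the chlorophyll list, whose lowest median under quantile and median scaling was 0.69, and for the mitochondria-encoded list, whose highest was -0.39, but not for the plastid-encoded list, where -0.11 lay within the 0.17 by which wild-type arrays differed. The list medians kept their direction in 24 of 24 combinations of 6 lists and 4 pairs of arrays, a count of signs alone; a single array was argued against for 5 lists, where each pair median was at least 0.29 in size and beyond the replicate difference, but not for the plastid-encoded list, where the pairs ranged from -0.47 to -0.048, the latter within 0.17. RNA integrity was tested for the plastid-encoded list only, and it remains open for all 6 lists. The plastid-encoded median was 0.17 higher on wild-type replicate 1 than on replicate 2, and the mitochondria-encoded median 0.14 higher. On wild-type replicate 1, 5 of 6 control 3' to 5' ratios were higher too, but the 2 sets of actin controls rank the wild-type arrays in opposite order. The 5S ribosomal RNA control was also highest on wild-type replicate 1, while the 25S control was not. A biological effect of the mutation or of the background remains open and untested.

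A hypothesis is that the jasmonate response may be lower in the mutant, since AT2G38240 and AT5G05600 were among the largest falls, although the call of AT5G05600 was lost without wild-type replicate 1 (limma adjusted p = 0.154) or 2 (0.0783). Of 42 other loci listed as jasmonate-inducible from general knowledge, 9 were tested, with a median log2 difference of -0.39, and 8 of 9 were below 0 (limma camera p = 0.00348; p = 0.359 with an estimated correlation). AT4G17470 and AT1G66100 passed the threshold, with log2 differences of -1.21 and -1.27. The tested loci include JAL33 and JAL34, which share a symbol family with JAL23, 1 of the largest falls. Since the list was written after those falls were seen, it is not independent of them. Without wild-type replicate 1 the median was -0.38, so the direction of the median does not rest on that array alone. The camera result for these loci was weaker without that array. The median difference between wild-type replicates 1 and 2 was 0.28 for these loci, so the size of the fall remains uncertain. Without mutant replicate 1 the median was -0.23, and without mutant replicate 2 it was -0.48. The preset jasmonate list had no tested member.

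A second hypothesis is that genes induced by sugar starvation may be lower in the mutant, since AT2G20670 and AT5G19120 were among the largest falls. Of 39 other such loci, also listed from general knowledge, 13 were tested, with a median of -0.45, and 12 of 13 were below 0 (limma camera p = 0.000276; p = 0.0613 with an estimated correlation). The leucine breakdown gene MCCA, the SnRK1 subunit gene AKINBETA1, AT3G15630 and AT3G15450 passed the threshold, with log2 differences of -1.09, -0.75, -0.72 and -0.71. IVD and MCCB, also of leucine breakdown, gave -0.37 and -0.02 and did not pass. Without wild-type replicate 1 the median was -0.46, which argues against that array alone. The number of loci past the threshold was 1 without mutant replicate 2 and 2 without wild-type replicate 2. Both hypotheses were formed and tested on the same 4 arrays.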
